A study of Mus musculus with 20 samples.

How the data were processed

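CUT&RUN libraries were made with a commercial kit (CUTANA CUT&RUN) and the NEBNext Ultra II library kit from nuclei of adult mouse whole brain that had been sorted by flow cytometry, per the labels' protocols. The gate that separated excitatory from inhibitory nuclei is not given in the sources used here. The 20 libraries fall into 10 groups of 2, 5 antibodies by 2 neuron types, and each sample's group and replicate number were taken from its title. Inside the EGR1 lists the peak names carry the numbers 3 and 4 where the labels say replicates 1 and 2; the labels were followed.

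Reads were trimmed, aligned and filtered and peaks were called by the authors, and the submitters' processing notes name cutadapt 1.18, Trim Galore 0.5.0, Bowtie2 2.3.5, Picard 2.25.0, SAMtools 1.12 and MACS2 2.2.5 and the mouse build mm10. Their settings and any control library are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were not called on pooled replicates: broad peaks for H3K4me1 and H3K27me3 and narrow peaks for the other antibodies. The deposited columns are a fold enrichment (a ratio) per peak, the -log10 p-value and -log10 q-value of the peak and an integer score. From the values, the deposited broad lists reach an unadjusted p of 0.0988 to 0.0999, the narrow histone lists 0.0483 to 0.0498 and the EGR1 lists 0.00481 to 0.00491. The lists were thus made with a lenient threshold for the histone marks, and many of their peaks do not pass a false discovery rate. They hold no read counts, so the depth of each library is unknown, no interval for counting error can be given, and the number of peaks depends on depth and enrichment as well as on biology. Fold and score entered no test.

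Peaks on chromosomes 1 to 19 and X were used at the deposited threshold, and positions are given 1-based on mm10. Overlapping peaks of the 4 libraries of an antibody were merged into union regions, and a library had a region if at least 1 base of its peaks lay in it. Similarity of libraries is the Jaccard index over bases. Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly mm10 is made from, with 21631 protein-coding genes. That table gives no strand and no genome sequence was used. The planned window of gene body plus 5 kb upstream was therefore replaced by the body plus 5 kb on both sides, for H3K4me1, H3K27ac and H3K27me3. The planned promoter window was replaced by 2 kb on each side of both gene ends, for H3K4me3 and EGR1, and bivalency was read at the same gene end. The planned search for the EGR1 motif was not run.

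For each antibody the percent of a gene's window covered by peaks was computed per library, quantile-normalized over the 4 libraries and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), for genes with at least 1 covered base in 2 or more libraries. The difference is excitatory minus inhibitory in percentage points of the window, on the normalized scale, while the levels given beside it are not normalized. Adjusted p-values are Benjamini-Hochberg over the genes of that antibody with a threshold of 0.05, and all tests are two-sided. Quantile normalization takes out differences in total coverage between libraries. The 2 other ways of splitting the 4 libraries into pairs served as background. In limma each side of these splits mixes the types, so a difference between types enters the residual spread and few calls can arise. Gene lists were tested with camera on the same fit with a preset correlation of 0.01 between genes and again with an estimated one, with Benjamini-Hochberg adjustment over 84 tests of 17 lists. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the genes. A call lost there can therefore reflect the few libraries and does not by itself show correlation between genes. The lists are excitatory forebrain neuron, inhibitory neuron, striatal projection neuron, thalamic, hypothalamic and brainstem neuron, cerebellar granule neuron, monoaminergic and cholinergic neuron, pan-neuronal, astrocyte, oligodendrocyte lineage, microglia, vascular, immediate early and EGR, glutamate receptor, GABA receptor and transporter, HOX cluster, chromatin-modifying enzyme and housekeeping genes. A gene list's members were counted over all genes tested and adjusted over the list alone. HOX genes with EGR1 had 1 tested member and no test.

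Genes named in the text were chosen by a rule. For each antibody and direction these are the 10 genes with the largest difference among those past an adjusted p of 0.05 whose libraries of one type all lie above those of the other, or, where fewer passed, up to 5 in the order of p. From each list and antibody up to 4 members with the largest difference were added, and Egr1, Slc17a7, Gad1 and Gad2 for every antibody. Gene models without a proper symbol were skipped, and the text names a part of the genes so chosen. Genes of the bivalent class are named as members of fixed lists.

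The share of EGR1 peaks with at least 1 base in a peak of a mark was computed for each pair of libraries and again after 100 circular shifts of the EGR1 peaks along their chromosomes. Type-specific EGR1 regions were set against type-specific regions of each mark with Fisher's exact test. The 2 sets of genes bivalent in one type were compared with each of the 17 lists by Fisher's exact test against all other genes, with Benjamini-Hochberg adjustment over both sets. Totals per library were compared with an exact permutation test. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

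The limma step was tested on simulated data with the real genes of each antibody, independent normal errors, spreads after limma's moderation and 200 changed genes. Of genes changed by 20 points it recovered 57% for H3K4me1, 100% for H3K4me3, 99% for H3K27ac, 21% for H3K27me3 and 100% for EGR1, and of genes changed by 40 points 99%, 100%, 100%, 92% and 100%. It called 12, 8, 11, 1 and 19 unchanged genes, and no changed gene with the wrong sign. The changed genes were drawn only from genes of high mean coverage. The shares recovered are therefore not the power of the test for other genes or for the spread of the real libraries.

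Groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. These alternatives were peaks with a -log10 q of at least 5, the same number of strongest peaks per library by q, no quantile normalization, a log2 scale of percent plus 1, the other gene window, no filter or a filter on coverage in all 4 libraries, a robust variance, the replicate number as a block, larger overlaps, narrower gene ends, and leaving out each library. Chosen after seeing the data were peaks with a -log10 p of at least 3, the gene end with more H3K4me3, and the coverage filters for gene lists. Also chosen then were the Fisher tests of the genes bivalent in inhibitory neurons alone and 3 further gene lists, for granule neurons, Purkinje cells and the granule list without genes of other lists. Some of the genes that the rule for named genes picks are not reported here. Peaks on the Y chromosome, the mitochondrial genome and unplaced contigs were left out of the comparisons.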

Results

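To compare chromatin and transcription factor binding between neuronal classes, CUT&RUN was carried out on nuclei sorted from the whole brain of 8-week-old mice. CUT&RUN releases and sequences the DNA bound by an antibody in intact nuclei. The mice carried a floxed Sun1 allele and an Emx1-driven Cre recombinase. Emx1 is a transcription factor of the dorsal forebrain, and Sun1 is a protein of the nuclear envelope. Antibodies against 4 histone modifications and against EGR1, an activity-induced zinc-finger transcription factor, were each applied to excitatory and to inhibitory neurons, with 2 libraries per group and 20 libraries in all. H3K4me1 is found at enhancers and in the bodies of active genes, H3K4me3 at promoters, H3K27ac at active promoters and enhancers, and H3K27me3 in regions repressed by Polycomb. Nothing in the labels says that the 2 libraries of a group came from separate animals, so limma p-values measure only the spread between these libraries. Camera p-values with the preset correlation rest on the number of genes, and Fisher p-values on counts of genes or regions. Neither measures the spread between libraries or animals. The lists hold called peaks and no read counts, so the sequencing depth of each library is unknown.

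The excitatory libraries held more EGR1 peaks than the inhibitory ones, with 93858 and 98534 against 49899 and 62412 peaks. These EGR1 peaks covered 49.5 Mb ± 1.02 (SD, n = 2) in excitatory and 26.1 Mb ± 5.07 (SD, n = 2) in inhibitory neurons, a ratio of 1.89. H3K4me1 peaks covered 237 Mb ± 27.5 against 175 Mb ± 17.3, and H3K27me3 peaks covered less of the genome in excitatory neurons, 199 Mb ± 23.8 against 260 Mb ± 23.9. H3K4me3 covered 58.7 Mb ± 14.7 in excitatory and 58.1 Mb ± 8.39 in inhibitory neurons, and H3K27ac 88.2 Mb ± 36.3 and 65.7 Mb ± 3.66. A two-sided exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none of these comparisons could pass a threshold. That smallest value, 0.333, was reached by covered length for EGR1, H3K4me1 and H3K27me3, and the exact p was 1 for H3K4me3 and H3K27ac. The share of peaks with a q-value below 0.05, as the authors' caller gave it, was 2.57% and 4.94% in the excitatory H3K27ac libraries and 31.8% and 35.1% in the inhibitory ones. In the EGR1 libraries it lay between 90.7% and 98.1%, and in the H3K27me3 libraries between 0.00488% and 0.00990%. The fold enrichment, score, p and q of each peak are the authors' values and were used only to describe, rank or filter peaks within a list.

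To ask whether peak positions separated the cell types beyond the difference between replicates, the Jaccard index of covered bases was computed for each pair of libraries. EGR1 peaks of the excitatory pair had an index of 0.526 and those of the inhibitory pair 0.396, against 0.293 ± 0.0224 (SD, 4 pairs) between the types. The corresponding values were 0.296, 0.424 and 0.211 ± 0.0210 for H3K4me1, and 0.209, 0.255 and 0.171 ± 0.0133 for H3K27me3. For H3K4me3 the excitatory pair, at 0.314, lay within the spread of the between-type pairs, 0.304 ± 0.0343, and the inhibitory pair stood at 0.415. The H3K27ac excitatory pair had an index of 0.113, below the between-type mean of 0.124 ± 0.0081, while the inhibitory pair reached 0.315. Of the 20 libraries, 16 were nearest to the other library of their own group and 18 to a library of the same antibody. The 2 excitatory H3K27ac libraries were nearest to excitatory EGR1 libraries, with indices of 0.166 and 0.154, and the 2 excitatory H3K4me3 libraries to replicate 2 of inhibitory H3K4me3, with 0.334 and 0.332.

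Regions with a peak in both libraries of one type and in neither of the other were then counted. EGR1 had 30308 excitatory-specific and 3479 inhibitory-specific regions, against 3600 and 3260 such regions in total for the 2 other ways of splitting the 4 libraries into pairs. A further 26345 EGR1 regions had a peak in all 4 libraries. H3K4me1 had 61575 excitatory-specific and 13391 inhibitory-specific regions (other splits 11109 and 9849), and H3K27me3 had 22184 and 37141 (other splits 23187 and 23042). H3K27ac had 24459 excitatory-specific and 15040 inhibitory-specific regions (other splits 12256 and 11218), and H3K4me3 had 7279 and 11398 (other splits 6090 and 6647). With the same number of strongest peaks taken from each library, the excess of excitatory EGR1 regions was 12053 against 6434. The order turned round for H3K4me1, with 24213 excitatory-specific and 26394 inhibitory-specific regions, and for H3K27ac, with 12769 and 20406. The inhibitory excess of H3K27me3 became 25799 against 26677.

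**Figure D1:**
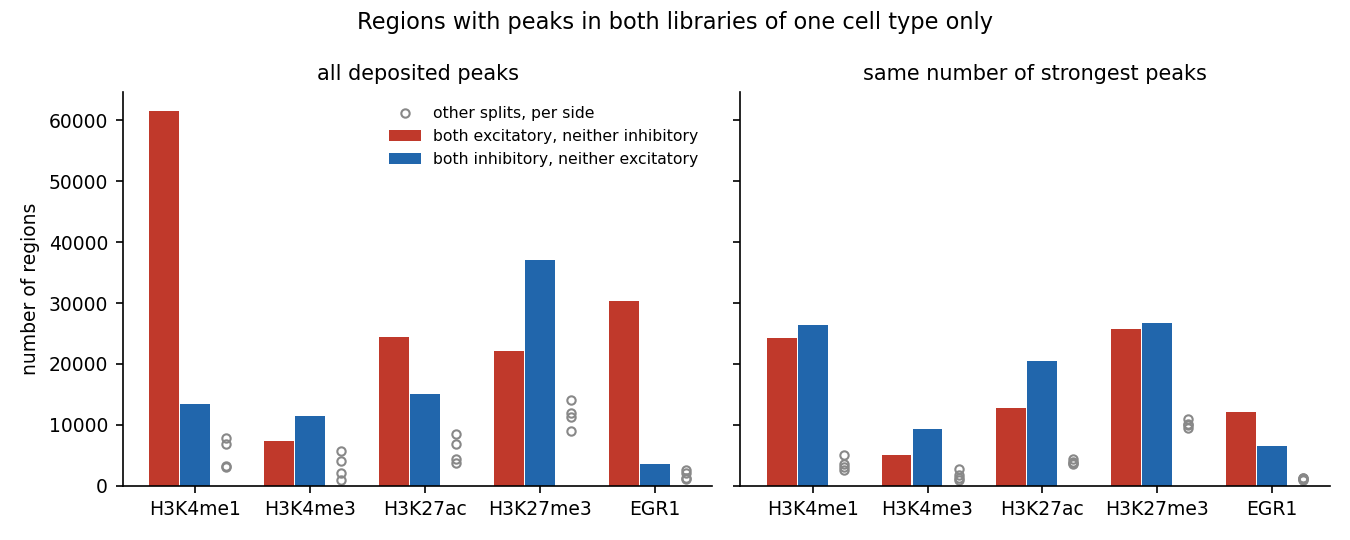
Number of regions (vertical axis) with peaks in both libraries of one cell type and in neither of the other, for each antibody, with all deposited peaks (left) and with the same number of strongest peaks per library (right). Red and blue bars are excitatory-specific and inhibitory-specific regions and open circles are the counts for each side of the 2 other splits of the 4 libraries; EGR1 has 30308 and 3479 regions on the left and 12053 and 6434 on the right.

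H3K4me1 over gene bodies was higher in excitatory neurons at Vgf, which encodes an activity-regulated secreted neuropeptide precursor (gene ID 381677, chromosome 5, 137025301 to 137033351, mm10). Its window was covered to 42.3% ± 10.3 (SD, n = 2) in excitatory and 6.20% ± 2.79 (SD, n = 2) in inhibitory libraries, a normalized difference of 35.0 percentage points ± 3.90 (SE) with a limma adjusted p of 0.0401. Kcna5, a voltage-gated potassium channel gene, rose by 30.9 points, and Tac2, which encodes neurokinin B, by 26.5. In the opposite direction, Tlx3, a homeobox gene that specifies excitatory neurons of the spinal cord and hindbrain, was covered to 5.49% ± 0.386 in excitatory and 37.9% ± 8.74 in inhibitory libraries, a difference of -32.9 points ± 3.94 (adjusted p = 0.0401). The homeobox genes Barhl2 and Hoxa7 had differences of -26.0 and -25.0 points, S100g, a calcium-binding protein gene, -36.1, and Zic5, a zinc-finger gene of the dorsal midline and cerebellum, -24.9.

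By limma, 732 of the 18017 genes tested for H3K4me1 passed an adjusted p of 0.05, 456 higher in excitatory and 276 higher in inhibitory neurons. The real split had 4672 genes at an unadjusted p under 0.05. With limma the other splits of the libraries gave 0 calls each, and 313 and 201 genes at that level. Each side of these splits mixes the types, so a difference between types widens the residual spread and holds these counts down. The splits are therefore a low background, here and for the other antibodies. Quantile normalization removes the larger coverage of the excitatory libraries. Without it 1043 were higher in excitatory and 168 in inhibitory neurons. The median difference over all genes then moved from -0.342 to 1.85 points. The count was 0 without excitatory replicate 1 (4375 genes at an unadjusted p under 0.05), 0 without inhibitory replicate 1 (2886), 0 without inhibitory replicate 2 (2737) and 507 without excitatory replicate 2. With the same number of strongest peaks per library limma called 0 genes (4025 at an unadjusted p under 0.05), and 0 with the replicate number as a block (4773).

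Of the gene lists fixed in advance, the excitatory forebrain list had a median H3K4me1 difference of 4.19 points, with 28 of 35 members higher in excitatory neurons (camera adjusted p = 0.00181). Its adjusted p was 0.683 with an estimated correlation between genes, and at gene ends its median was -1.40 (adjusted p = 0.541). Without excitatory replicate 2 its median was 2.54 (adjusted p = 0.0458). Ldb2, a cofactor of LIM-homeodomain proteins, was the 1 member that rose over all genes tested, by 17.0 points, and 7 rose adjusted over the list alone. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons (chromosome 7, 45163921 to 45176139), had a difference of 2.21 ± 2.69 (adjusted p = 0.649). Glutamate receptor genes had a median of 5.43 with 16 of 22 higher in excitatory neurons (adjusted p = 0.00382, and adjusted p = 0.683 with an estimated correlation). Of these, 7 rose over all genes, and 12 rose and 3 fell adjusted over the list alone. The AMPA receptor subunit gene Gria1 rose, with 3.27% ± 1.27 in inhibitory and 24.9% ± 5.47 in excitatory libraries. GABA receptor and transporter genes had a median of 6.88 with 11 of 17 higher (adjusted p = 0.00449, and adjusted p = 0.659 with an estimated correlation). The 4 that rose over all genes include the GABA transporter gene Slc6a11, by 17.3 points, and the receptor subunit gene Gabra2, by 13.9, and 9 rose adjusted over the list alone. At gene ends the glutamate and GABA lists had medians of -4.30 (adjusted p = 0.328) and -0.700 (adjusted p = 0.615), and Ldb2 and Gabra2 had differences of -8.22 and -7.86. With equal peak numbers the excitatory, glutamate and GABA lists had medians of 2.15 (adjusted p = 0.129), 3.89 (adjusted p = 0.0595) and 2.29 (adjusted p = 0.141). Their adjusted p was 0.144, 0.0529 and 0.429 with peaks of -log10 p of at least 3.

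HOX cluster genes, which pattern the hindbrain and spinal cord, had less H3K4me1 in excitatory neurons at all 33 tested members (29 of 33 without quantile normalization), with a median of -7.32 points (adjusted p = 2.40e-09, and adjusted p = 0.678 with an estimated correlation). Members of a cluster are neighbours whose windows can overlap, so the 33 are not independent. Their estimated correlation was 0.261, above the preset 0.01. Hoxc9 and Hoxd10, with differences of -19.3 and -17.3, were among 7 that fell over all genes, and 17 fell adjusted over the list alone. Genes of thalamic, hypothalamic and brainstem neurons had a median of -7.28 with 19 of 28 lower (adjusted p = 0.00449, and adjusted p = 0.635 with an estimated correlation). The homeobox gene Otx2, at -24.4, was among 6 that fell over all genes, and 11 fell and 1 rose adjusted over the list alone. Cerebellar granule neuron genes had a median of -7.97 with 18 of 20 lower (adjusted p = 1.09e-04, and adjusted p = 0.635 with an estimated correlation), and at gene ends -4.32 (adjusted p = 0.129). Gabra6, a GABA receptor subunit gene of granule cells (chromosome 11, 42306437 to 42321072), was covered to 6.53% ± 1.79 in excitatory and 24.0% ± 0.232 in inhibitory libraries. It was 1 of 4 that fell over all genes and 7 that fell adjusted over the list alone. The inhibitory neuron list did not pass, with a median of 2.53 (adjusted p = 0.163), 5 members that rose and 3 that fell. Gad1, which encodes a GABA-synthesizing enzyme (chromosome 2, 70561303 to 70602014), was among the risers, with 23.3% ± 2.94 in excitatory and 5.91% ± 2.11 in inhibitory libraries (adjusted p = 0.0496), together with Kit, at 14.3. Sp8 and Nkx2-1, regulators of interneuron development, had differences of -19.4 and -14.6. Gad2, the gene of the other GABA-synthesizing enzyme, had a difference of 9.98 ± 2.32 (adjusted p = 0.0704).

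H3K4me3 at gene ends was higher in excitatory neurons at Sstr4, a somatostatin receptor gene (gene ID 20608, chromosome 2, 148395377 to 148396764), with 56.5% ± 8.92 (SD, n = 2) of the window covered against 7.64% ± 6.08 (SD, n = 2) in inhibitory neurons. The difference was 47.6 points ± 5.04 (limma adjusted p = 0.0130). Oprd1, the delta opioid receptor gene, rose by 30.1 points, Cacng3, an AMPA receptor auxiliary subunit gene, by 29.3, and Pde2a, a cyclic nucleotide phosphodiesterase gene, by 28.2. Tbr1, a T-box gene of cortical glutamatergic neurons (gene ID 21375, chromosome 2, 61802863 to 61814114), went the other way, with 0 and 12.0% in the excitatory and 34.3% and 35.9% in the inhibitory libraries, a difference of -29.9 points ± 3.22 (adjusted p = 0.0138). Eomes, a T-box gene of intermediate progenitors and unipolar brush cells, had -29.5, Gabra6 -27.3 ± 2.77, and Mdk, a heparin-binding growth factor gene, -26.5.

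For H3K4me3, 474 of 15685 genes passed limma's test, 282 higher in excitatory and 192 higher in inhibitory neurons, with 2758 genes at an unadjusted p under 0.05. The other splits gave 0 calls each with 285 and 195 genes at that level. Without excitatory replicate 1 the count was 733, and it was 0 without excitatory replicate 2 (3280 genes at an unadjusted p under 0.05), 0 without inhibitory replicate 1 (1396), 0 without inhibitory replicate 2 (1540) and 0 without quantile normalization (2344). It was also 0 on a log2 scale (2774) and with peaks of -log10 q of at least 5 (1251), and 1247 with the replicate number as a block.

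Cerebellar granule neuron genes had a median H3K4me3 difference of -14.1 points with 17 of 20 lower in excitatory neurons (adjusted p = 8.53e-09, and adjusted p = 0.635 with an estimated correlation). Of the list, 8 fell over all genes tested, Barhl1, a homeobox gene of granule cells, with -23.5. In this list 13 fell adjusted over the list alone. Atoh1, the basic helix-loop-helix gene that specifies granule cells, had a difference of -27.7 ± 5.77 (adjusted p = 0.0599). The thalamic, hypothalamic and brainstem list had a median of -7.10 with 22 of 27 lower (adjusted p = 2.63e-06, and adjusted p = 0.635 with an estimated correlation). Barhl2, Otx2, Irx1 and Nkx2-4, homeobox genes with differences of -21.5 to -19.0, were among 6 that fell over all genes, and 14 fell and 1 rose adjusted over the list alone. Astrocyte genes had a median of -3.89 with 12 of 14 lower (adjusted p = 0.00401, and adjusted p = 0.635 with an estimated correlation). Slc4a4, a bicarbonate transporter gene, was the 1 that fell over all genes, with -19.5, and 2 fell adjusted over the list alone. GABA receptor and transporter genes had a median of 2.45 with 11 of 17 higher (adjusted p = 0.0123, adjusted p = 0.678 with an estimated correlation, and adjusted p = 0.0646 without excitatory replicate 2). The receptor subunit gene Gabrg3 rose over all genes, by 19.03 points. In this list 6 rose adjusted over the list alone. Striatal projection neuron genes had a median of 3.22 with 15 of 18 higher (adjusted p = 0.0453, and adjusted p = 0.678 with an estimated correlation). The dopamine receptor gene Drd1 rose by 25.2 points and Ebf1, a transcription factor gene, had -13.5, and adjusted over the list alone 3 rose and 1 fell. The striatal median was 5.12 (adjusted p = 0.00649) without excitatory replicate 1, 1.99 (adjusted p = 0.270) without excitatory replicate 2, 2.10 (adjusted p = 0.207) without inhibitory replicate 1 and 3.46 (adjusted p = 0.0517) without inhibitory replicate 2. Its adjusted p was 0.0827 with the same number of strongest peaks and 0.0598 without quantile normalization. The camera adjusted p was 0.0552 on the log2 scale, 0.138 among genes covered in all 4 libraries and 0.425 with peaks of -log10 p of at least 3. It was 0.0660 at the gene end with more H3K4me3. The call was kept over gene bodies (0.00637), with no filter on coverage (0.0414) and with the replicate number as a block (0.0438). When only peaks with a -log10 q of at least 5 were used, the granule median was 9.22 (adjusted p = 0.693), the striatal -6.65 (adjusted p = 0.101), the GABA -5.73 (adjusted p = 0.620), the thalamic -4.93 (adjusted p = 0.0740) and the astrocyte -2.99 (adjusted p = 0.114). Over gene bodies the thalamic, astrocyte and GABA medians were -0.677 (adjusted p = 0.185), -0.365 (adjusted p = 0.547) and 0.722 (adjusted p = 0.149).

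The excitatory and inhibitory lists did not pass for H3K4me3, with medians of 2.35 (adjusted p = 0.664) and -2.26 (adjusted p = 0.397). The excitatory list passed with peaks of -log10 q of at least 5, in the direction of less H3K4me3 in excitatory neurons, with a median of -9.94 and 14 of 17 members lower (adjusted p = 2.57e-06). Its median was -1.05 without excitatory replicate 2 (adjusted p = 0.754), and that of the inhibitory list was 0.0174 without excitatory replicate 1. In the excitatory list the potassium channel gene Kcnv1 and Ldb2 rose, by 18.9 and 16.1 points, and Tbr1 fell. In the inhibitory list 2 members rose over all genes and 1 fell, Calb2, the calretinin gene, with -21.1. Slc17a7 had a difference of -14.6 ± 5.37 (adjusted p = 0.222), Gad1 -1.63 ± 2.19 (adjusted p = 0.773) and Gad2 -10.1 ± 2.52 (adjusted p = 0.0921). Single members of lists that did not pass include Homer1 and Grin1, genes of the glutamatergic synapse, with -21.7 and -21.6, and Syn1, which encodes a synaptic vesicle protein, with -16.4. The adhesion gene Nrxn3 rose by 21.3 points at gene ends and had -1.45 over its body.

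For H3K27ac no gene passed limma's test among 16654, with a lowest adjusted p of 0.144 and 3039 genes at an unadjusted p under 0.05, against 306 and 256 in the other splits. The count was 925 without excitatory replicate 1, 899 without excitatory replicate 2, 0 without inhibitory replicate 1 (1043 at an unadjusted p under 0.05) and 0 without inhibitory replicate 2 (1132). With the replicate number as a block 1329 genes passed, but there limma used the mean-variance trend in place of each gene's own spread. With peaks of -log10 q of at least 5 the count was 529 of the 929 then tested, 315 higher in excitatory and 214 in inhibitory neurons. At that cut the excitatory libraries held 14 and 42 peaks and the inhibitory ones 2273 and 3276. Quantile normalization brings such nearly empty libraries to the distribution of the fuller ones, so these 529 cannot be read as differences between the types. In the order by p, Phlda3, a p53 target gene, had 16.5% ± 0.222 (SD, n = 2) in excitatory libraries and was listed at 0 in both inhibitory ones, a difference of 17.9 points ± 1.69 (limma adjusted p = 0.144). Fam43b had 14.7 ± 1.66, Mdk -17.7 and Zdhhc25, of a palmitoyltransferase family, -20.5 ± 1.97, each with the same adjusted p.

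The inhibitory neuron list had more H3K27ac in excitatory neurons, with a median of 2.86 points and 25 of 31 members higher (adjusted p = 8.16e-04, and adjusted p = 0.635 with an estimated correlation). Slc32a1, the vesicular GABA transporter gene (chromosome 2, 158607260 to 158615747), had 9.03% ± 1.97 in excitatory libraries and 0 in both inhibitory ones (difference 8.90 ± 2.22, adjusted p = 0.163), Gad1 2.86 ± 1.94 and Gad2 3.22 ± 0.920. None of this list passed adjusted over the list alone. The excitatory forebrain list had a median of 2.08 with 23 of 33 higher (adjusted p = 0.00314, adjusted p = 0.683 with an estimated correlation, and a median of 1.08 with adjusted p = 0.155 without excitatory replicate 1), and 9 members rose adjusted over the list alone, among them Kcnv1, by 10.4 points, and the LIM-homeobox gene Lhx2, by 9.04. Striatal projection neuron genes had a median of 3.92 with 12 of 16 higher (adjusted p = 0.00244, and adjusted p = 0.635 with an estimated correlation). In this list 6 rose and 1 fell adjusted over the list alone, with 9.75 at Drd1 and 8.38 at the enkephalin gene Penk. Oligodendrocyte genes had a median of 2.255 with 10 of 13 higher (adjusted p = 0.0129, and adjusted p = 0.635 with an estimated correlation). With no filter on coverage their median was 0.550 with 12 of 19 higher (adjusted p = 0.0612). Adjusted over the list alone 5 rose, with a difference of 6.16 at Mog, a myelin gene. Glutamate receptor genes had 1.91 with 14 of 22 higher (adjusted p = 0.0155, and adjusted p = 0.635 with an estimated correlation), and 4 rose adjusted over the list alone. Without inhibitory replicate 2 the adjusted p of this list was 0.0844. GABA receptor and transporter genes had 1.68 with 11 of 17 higher (adjusted p = 0.0255, and adjusted p = 0.683 with an estimated correlation), and 6 rose adjusted over the list alone. Its adjusted p was 0.196 without excitatory replicate 1, at a median of 0.0440, and 0.152 without inhibitory replicate 2, and its median was 3.21 without excitatory replicate 2. Granule neuron genes went the other way, with a median of -4.27 and 17 of 19 lower (adjusted p = 7.68e-04, and adjusted p = 0.659 with an estimated correlation). Zic5 had -10.9 and the homeobox gene En2 -10.7, and 2 fell adjusted over the list alone. With peaks of -log10 p of at least 3 the medians were 0.977 (adjusted p = 0.300) for inhibitory, 1.17 (adjusted p = 0.0798) for excitatory, 1.27 (adjusted p = 0.458) for striatal and 1.85 (adjusted p = 0.130) for oligodendrocyte genes. At gene ends the excitatory, striatal and oligodendrocyte medians were 2.84 (adjusted p = 0.149), 4.42 (adjusted p = 0.420) and 5.60 (adjusted p = 0.342). Among genes covered in all 4 libraries the adjusted p was 0.0753 for the inhibitory, 0.0666 for the excitatory, 0.348 for the striatal, 0.348 for the oligodendrocyte and 0.383 for the GABA list, whose median was then -0.159. Among single genes, Arc, a synaptic immediate early gene, had 4.97% ± 3.48 in excitatory and 22.7% ± 3.53 in inhibitory libraries (adjusted p = 0.144), and Slc17a7 7.58% ± 0.442 and 14.2% ± 0.321 (adjusted p = 0.260).

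For H3K27me3 no gene passed limma's test among 15438, with a lowest adjusted p of 0.0555 and 4455 genes at an unadjusted p under 0.05, against 316 and 248 in the other splits. On a log2 scale 1031 genes passed, and 1167 of the 10034 covered in all 4 libraries. The largest values in the order by p were at Zic2, a zinc-finger gene of the dorsal neural tube and cerebellum (gene ID 22772, chromosome 14, 122475384 to 122480328), with 35.7% ± 0.383 (SD, n = 2) in excitatory libraries and 0 in both inhibitory ones, a difference of 37.1 points ± 2.29 (limma adjusted p = 0.0555). Calb2 had 28.8% ± 2.52 in excitatory and 0.829% ± 1.17 in inhibitory libraries. The neighbouring histone genes H2bc7 and H2ac7, whose windows overlap, had 34.2% ± 0.555 and 32.8% ± 1.07 in inhibitory libraries and 0 in excitatory ones. Pdgfb, a growth factor gene, had 35.1% ± 1.34 against 1.95% ± 0.750. Granule neuron genes had more H3K27me3 in excitatory neurons, with a median of 20.8 points and 16 of 19 members higher (adjusted p = 1.70e-08, and adjusted p = 0.635 with an estimated correlation). None passed over all genes tested, and 15 rose adjusted over the list alone. Neurod1, a basic helix-loop-helix gene of granule and cortical excitatory neurons (chromosome 2, 79452637 to 79456636), had 34.3% ± 4.39 and 0, a difference of 35.8 ± 3.79, Zic5 35.3 ± 3.03 and En2 33.1 ± 5.73. Among the 6 granule genes covered in all 4 libraries the median was 2.94 (adjusted p = 0.380), a filter that leaves out every gene at 0 in a library. The excitatory list had a median of 0.380 (adjusted p = 0.610; -0.326 without excitatory replicate 1 and -2.45 without quantile normalization), with Neurod2 at 25.9 ± 3.16 and Camk2a, a synaptic kinase gene, at -17.8 ± 3.07. The inhibitory list had 2.69 with 25 of 37 higher (adjusted p = 0.0927), with Prox1 at 28.6 and Reln at 20.2. Without quantile normalization the inhibitory list's median was -0.922 while all genes moved from a median of 0.0498 to -2.06. Thy1, a neuronal surface protein gene, was at 0 in both excitatory and 24.7% ± 2.41 in inhibitory libraries, and the NMDA receptor subunit genes Grin2b and Grin2c had -23.6 ± 2.54 and 29.8 ± 3.15.

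EGR1 binding at gene ends gave no limma call among 14310 genes, with a lowest adjusted p of 0.107 and 2105 genes at an unadjusted p under 0.05, against 316 and 347 in the other splits. Over gene bodies 432 genes passed, 344 higher in excitatory and 88 higher in inhibitory neurons. In the order by p at gene ends, Cpxm2, of the carboxypeptidase family (gene ID 55987, chromosome 7, 132032687 to 132154765), had 24.0% ± 2.72 (SD, n = 2) in excitatory libraries and 0 in both inhibitory ones, a difference of 20.4 points ± 1.98 (limma adjusted p = 0.107). Erbb4, a neuregulin receptor gene of interneurons (gene ID 13869, chromosome 1, 68031884 to 69108576), had 0 in both excitatory and 11.2% ± 1.87 in inhibitory libraries, a difference of -12.6 ± 1.47. Rhbdl3, of the rhomboid protease family, had -18.3 ± 1.63. Excitatory forebrain genes had more EGR1 in excitatory neurons, with a median of 2.33 and 22 of 33 members higher (adjusted p = 0.00340, and adjusted p = 0.635 with an estimated correlation), and 7 rose adjusted over the list alone. The median was 0.946 without excitatory replicate 1 (adjusted p = 0.0107) and 0.980 with peaks of -log10 q of at least 5 (adjusted p = 0.0471). Lhx2 (chromosome 2, 38339271 to 38369737) had 23.4% ± 2.40 against 3.56% ± 0.804, Neurod6 a difference of 11.9 ± 1.89, Kcnv1 10.7 ± 2.12 and Emx1 10.4 ± 1.48. Slc17a7 had 17.2% ± 1.31 against 7.44% ± 0.955 (adjusted p = 0.167). Coverage does not measure the strength of a peak. By fold within each list, the peak before its start coordinate ranked at 67.0% and 88.9% from the top in excitatory libraries. In inhibitory libraries it ranked at 7.93% and 7.22%, the opposite direction to coverage. Inhibitory neuron genes had less, with a median of -3.19 and 18 of 25 lower (adjusted p = 0.00382, and adjusted p = 0.635 with an estimated correlation), and 7 fell and 1 rose adjusted over the list alone. Gad1 was at 0 in both excitatory and 5.30% ± 2.85 in inhibitory libraries (difference -6.55 ± 1.36), Gad2 had -7.42 ± 1.39 and Slc32a1 -8.14 ± 1.60. Lamp5, a gene of neurogliaform interneurons and of some cortical excitatory neurons, had 10.3 ± 1.76. The median of this list was -0.469 without quantile normalization, its adjusted p was 0.0578 without inhibitory replicate 2, and with peaks of -log10 q of at least 5 it was 0.638. Granule neuron genes had a median of -2.97 with 10 of 16 lower (adjusted p = 0.0324, and adjusted p = 0.683 with an estimated correlation), and 2 fell adjusted over the list alone. Without quantile normalization all genes moved from a median of -0.427 to 2.35. The inhibitory and granule lists lay below that median and both calls were kept (camera adjusted p = 7.47e-06 and 0.00458). The granule median was then 0.0719. It was -1.78 (adjusted p = 0.0946) without excitatory replicate 1, -4.70 (adjusted p = 0.0130) without inhibitory replicate 1 and -2.72 (adjusted p = 0.472) without inhibitory replicate 2. Its adjusted p was 0.379 with peaks of -log10 q of at least 5. Among genes covered in all 4 libraries the granule median was 0.590 (adjusted p = 0.936) and the inhibitory -0.950 (adjusted p = 0.320), so that neither passed. Zic1 and Zic4, neighbours whose windows overlap, each had -10.4 ± 1.48. Egr1 itself (gene ID 13653, chromosome 18, 34861207 to 34864956) was covered to 22.9% ± 1.94 in excitatory and 22.9% ± 1.40 in inhibitory EGR1 libraries (normalized difference -4.54 ± 2.77, limma adjusted p = 0.504), with a peak within 2 kb before its start coordinate in all 4 libraries.

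Across antibodies, 22 of 84 list tests passed with the preset correlation and 0 with an estimated one. The second test has few degrees of freedom, so it cannot tell whether correlation between genes ends these calls. For the granule list in H3K27me3 the estimated correlation was -0.00305, below the preset 0.01. Its unadjusted camera p nevertheless went from 6.05e-10 to 0.0214. The granule neuron list passed for all 5 antibodies, lower in excitatory neurons for H3K4me1, H3K4me3, H3K27ac and EGR1 and higher for H3K27me3. Of its 20 genes 5 are also in other lists. Of the excitatory list 3 of 35 genes, of the inhibitory 4 of 40, of the glutamate receptor 3 of 22 and of the GABA 3 of 17 are shared with another list. Pan-neuronal genes had medians from -1.57 for EGR1 to 0.446 for H3K4me1, with a lowest adjusted p of 0.335 for H3K4me3. Microglial genes did not pass (H3K27ac median 1.52, adjusted p = 0.127), nor did vascular (H3K4me3 median -2.88, adjusted p = 0.375), monoaminergic and cholinergic (H3K27me3 median 2.18, adjusted p = 0.363) or immediate early and EGR genes (H3K4me3 median -0.445, adjusted p = 0.343). Genes of chromatin-modifying enzymes had an H3K4me3 median of -2.21 (adjusted p = 0.117) and housekeeping genes -3.68 (adjusted p = 0.117), the lowest adjusted p of each. For the HOX cluster the other medians were 1.66 for H3K4me3 (adjusted p = 0.251), 0.252 for H3K27ac (adjusted p = 0.765, 4 genes) and 2.71 for H3K27me3 (adjusted p = 0.375). Median, mean and test differed in sign in 11 of the 84 tests, none of which passed, among them thalamic genes for H3K27ac, with a median of 0.483 and a mean of -0.848, and immediate early genes for EGR1, with -0.511 and 0.496.

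**Figure D2:**
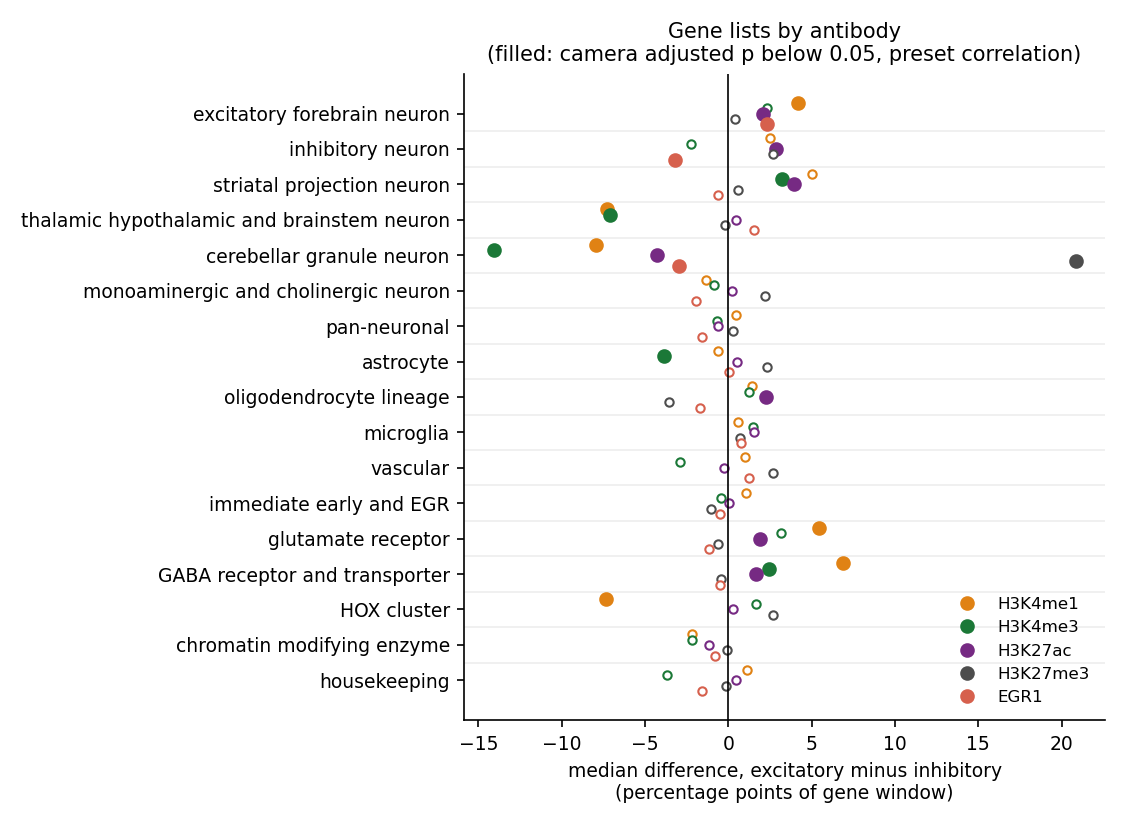
Median difference in coverage of the gene window between excitatory and inhibitory libraries (horizontal axis, percentage points) for each gene list and antibody. Filled points have a camera adjusted p below 0.05 with the preset correlation, none of which holds with an estimated correlation; the granule neuron list lies at 20.8 for H3K27me3 and at -14.1 for H3K4me3.

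**Figure D3:**
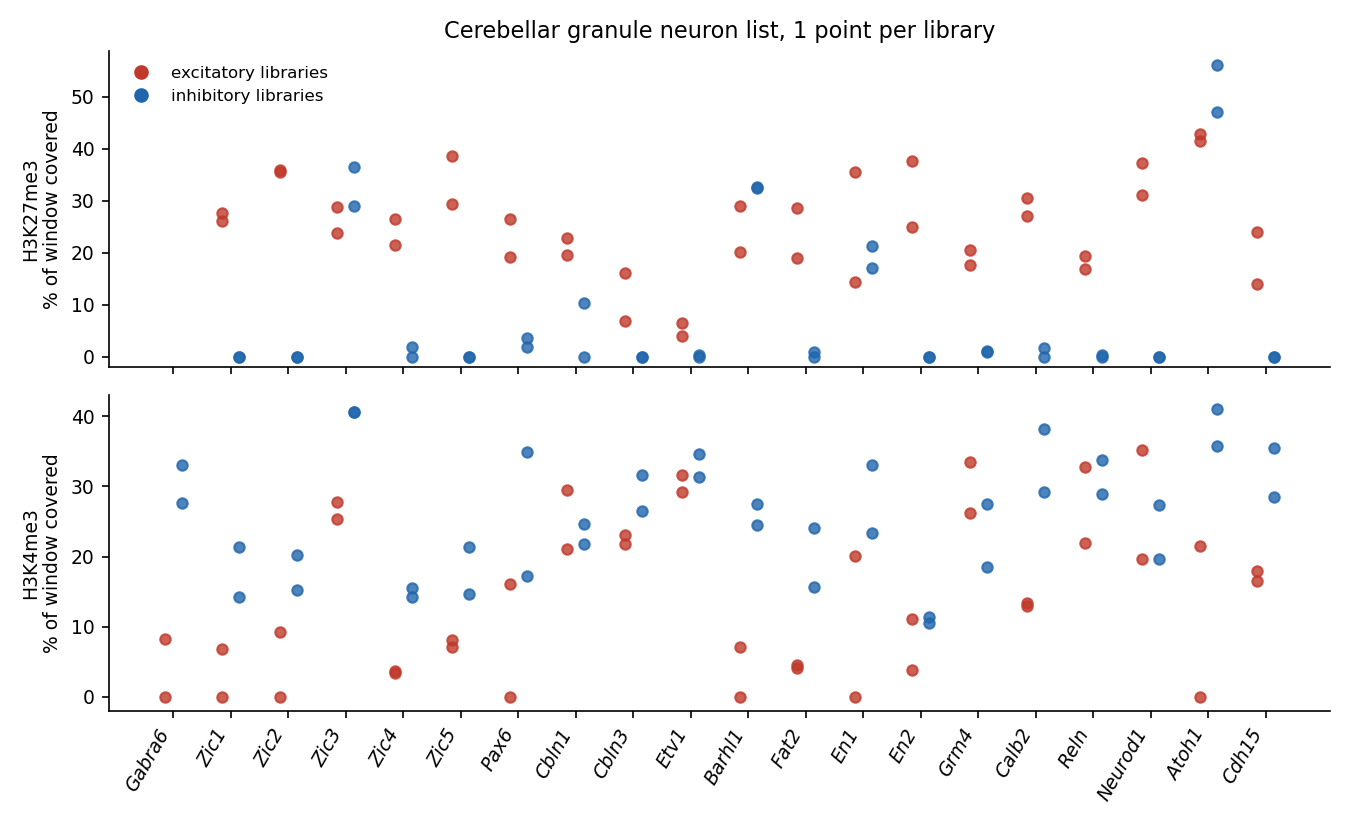
Percent of the gene window covered by H3K27me3 peaks (top) and H3K4me3 peaks (bottom) for each gene of the cerebellar granule neuron list, with 1 point per library, excitatory in red and inhibitory in blue. A gene outside a test has no point there; Zic2 has 35.4% and 36.0% H3K27me3 in excitatory and 0 in both inhibitory libraries.

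To ask how EGR1 sites and histone marks coincide within a cell type, EGR1 peaks were overlapped with the peaks of each mark. In excitatory neurons 74.0% ± 4.66 (SD, 4 pairs of libraries) of EGR1 peaks met an H3K4me1 peak, 50.3% ± 8.18 an H3K27ac peak, 41.1% ± 11.1 an H3K4me3 peak and 16.2% ± 2.07 an H3K27me3 peak. After circular shifts of the EGR1 peaks along their chromosomes these shares were 15.5%, 7.60%, 4.82% and 13.1%. In inhibitory neurons the shares were 54.2% ± 3.03 for H3K4me1, 53.0% ± 1.91 for H3K27ac, 55.2% ± 0.915 for H3K4me3 and 25.1% ± 0.629 for H3K27me3, with 10.3%, 4.65%, 4.55% and 16.0% after shifting. Set against the marks of inhibitory neurons, the excitatory EGR1 peaks had shares of 44.1% ± 2.16 for H3K4me1, 35.2% ± 1.52 for H3K27ac, 35.6% ± 0.939 for H3K4me3 and 27.9% ± 0.897 for H3K27me3. Inhibitory EGR1 peaks met excitatory marks at 67.3% ± 4.83 for H3K4me1, 55.2% ± 7.52 for H3K27ac, 52.0% ± 10.4 for H3K4me3 and 17.2% ± 1.80 for H3K27me3. By share, inhibitory EGR1 peaks thus met excitatory H3K4me1 more often than inhibitory H3K4me1. For H3K27ac and H3K4me3 their shares with the marks of either type lay within the spread. These shares also depend on how much of the genome the peaks of a mark cover. Taken as a ratio to the share after shifting, the H3K4me1 order turned round, with 4.48 for excitatory and 5.27 for inhibitory H3K4me1. The ratios were 7.6 and 11.4 for H3K27ac, 11.3 and 12.1 for H3K4me3, and 1.36 and 1.57 for H3K27me3. The differences between these shares or ratios were not tested. With peaks of -log10 p of at least 3 the excitatory H3K4me1 share was 2.72% and the H3K27me3 share 0.130%.

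To ask whether type-specific EGR1 regions carried marks specific to the same type, the directions were set against each other. Of the excitatory-specific EGR1 regions that held a type-specific H3K4me1 region, 11751 had it in excitatory and 245 in inhibitory neurons, against 495 and 210 for inhibitory-specific EGR1 regions (odds ratio 20.3, two-sided Fisher exact p = 3.99e-148). With the same number of strongest peaks the inhibitory-specific EGR1 regions had 516 and 907, so that inhibitory H3K4me1 then prevailed there, at an odds ratio of 20.2. When only peaks with a -log10 p of at least 3 were used, inhibitory H3K4me1 prevailed at both classes, with 42 and 463 at excitatory-specific against 3 and 288 at inhibitory-specific EGR1 regions (odds ratio 8.71, Fisher exact p = 3.69e-06). The odds ratio was 16.1 for H3K27ac (4809 and 661 against 259 and 572, Fisher exact p = 2.28e-255) and 25.5 for H3K4me3 (1628 and 458 against 91 and 652, Fisher exact p = 5.07e-228). H3K27me3 went the other way, with 366 excitatory-specific and 2734 inhibitory-specific H3K27me3 regions at excitatory EGR1 regions against 159 and 175, an odds ratio of 0.147 (Fisher exact p = 1.29e-50). Regions along a chromosome are not independent replicates, so these p-values describe the regions of these libraries. Excitatory-specific H3K4me1 was found at 38.8% of the 30308 excitatory EGR1 regions, H3K27ac at 15.9% and H3K4me3 at 5.37%. H3K4me1 peaks met 82.1% ± 6.05 (SD, n = 2) of the excitatory-specific EGR1 regions in excitatory and 34.0% ± 2.95 in inhibitory libraries. At inhibitory-specific EGR1 regions the 2 types were closer, with 70.1% ± 8.39 and 64.3% ± 1.77. Within 2 kb of a gene end lay 7.11% of excitatory-specific, 9.05% of inhibitory-specific and 42.9% of the EGR1 regions in all 4 libraries.

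**Figure D4:**
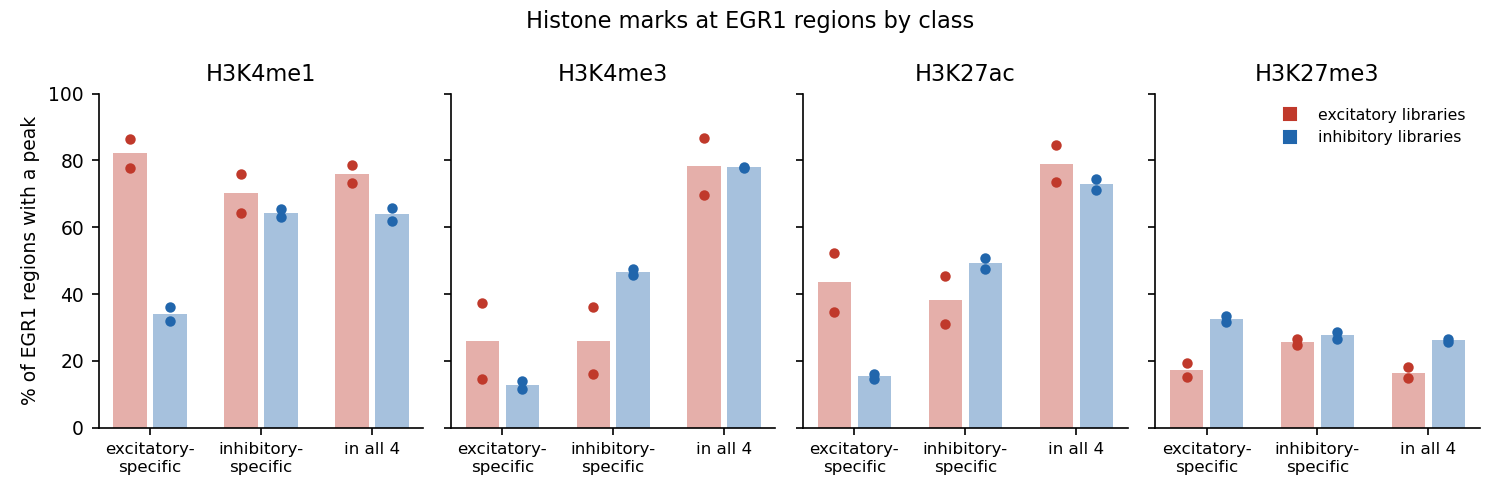
Share of EGR1 regions (vertical axis, percent) that meet a peak of each histone mark, for regions specific to excitatory neurons, specific to inhibitory neurons or present in all 4 EGR1 libraries. Bars are means of 2 libraries and points single libraries, excitatory in red and inhibitory in blue; H3K4me1 meets 82.1% of excitatory-specific regions in excitatory and 34.0% in inhibitory libraries.

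Bivalent genes, with H3K4me3 and H3K27me3 peaks in both libraries of each mark at the same gene end, numbered 3437 in excitatory neurons, 24.2% of 14196 genes with H3K4me3, and 4408 in inhibitory neurons, 31.3% of 14089. Both types shared 2513 of them. Bivalent in excitatory neurons with no H3K27me3 at either gene end in inhibitory libraries were 180 genes, and the reverse held for 789, against 30 to 64 genes for the groups of the other splits. Both sets were compared with the 17 gene lists by two-sided Fisher exact tests, adjusted over the 34 tests. The 180 include 5 of 20 granule neuron genes, Fat2, Neurod1, Reln, En2 and Cdh15 (Fisher adjusted p = 1.80e-05, background 0.832% of genes), and 4 of 35 excitatory forebrain genes, Neurod2, Nptx1, Neurod1 and Sv2b (Fisher adjusted p = 0.00337). Of the immediate early list they include Egr4 and Ier2, 2 of 27 (Fisher adjusted p = 0.179). The 789 include 4 of 17 GABA receptor and transporter genes, Gabbr2, Gabra4, Gabrb1 and Gabra3 (Fisher adjusted p = 0.0324, background 3.65% of genes), and 3 of 19 pan-neuronal genes, Nefm, Elavl4 and Thy1 (Fisher adjusted p = 0.206). H3K27me3 peaks covered 260 Mb in inhibitory and 199 Mb in excitatory neurons, which bears on the 180 and 789. With the same number of strongest peaks these were 219 and 603. H3K4me3 and H3K27me3 come from separate libraries, so whether both lie on the same chromatin was not tested. With peaks of -log10 p of at least 3 the bivalent genes numbered 7 and 48.

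Differences between the cell types were related across genes for the 10 pairs of antibodies, as a description in which genes are not independent replicates. With the windows of the gene tests, H3K4me1 and H3K27ac had the highest Spearman correlation, 0.451, followed by H3K4me1 and H3K4me3, 0.289, and H3K4me3 and H3K27ac, 0.279. H3K27me3 was negatively related to H3K27ac, at -0.313, to H3K4me1, at -0.294, and to H3K4me3, at -0.234. EGR1 had weaker relations with H3K4me1, 0.142, H3K4me3, 0.120, H3K27ac, 0.108, and H3K27me3, -0.0887. With the window at gene ends for all antibodies the order changed, with 0.302 for H3K4me3 and H3K27ac above 0.242 for H3K4me1 and H3K27ac.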

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

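Chosen after the main results were seen were the test of labels exchanged in the histone libraries alone, the further list of granule genes and the peaks with a -log10 p of at least 3. No group has more than 2 libraries, so no library was tested against the others of its group. Peaks outside chromosomes 1 to 19 and X entered no comparison and are given because they lie in data not otherwise used. The 20 lists hold 366 peaks on chromosome Y, between 1 and 52 per library, with 1 to 3 in the EGR1 lists and 18 to 52 in the H3K4me3 lists. They hold 106 peaks on the mitochondrial genome, between 1 and 12 per library, and 744 on unplaced and random contigs, between 15 and 87 per library.

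Cerebellar granule neuron genes had less H3K4me1, H3K4me3 and H3K27ac and more H3K27me3 in the libraries labelled excitatory, calls that are lost with an estimated correlation (adjusted p = 0.635 for H3K4me1, H3K4me3 and H3K27me3 and 0.659 for H3K27ac). With the same number of strongest peaks the H3K27me3 median of the list was 20.6 points against 20.8. Those of H3K4me1, H3K4me3 and H3K27ac were -9.98, -14.4 and -4.98. For H3K27me3 this cut mainly trims the inhibitory libraries, at or near 0 for most of these genes, so it cannot test peak number. For H3K4me1 and H3K27ac it mainly trims the excitatory libraries, which were already lower. The direction argues against peak number, since excitatory libraries held fewer H3K27me3 peaks (239030 against 289602). They held more H3K4me1 (292311 against 174602) and H3K27ac peaks (204390 against 112207). Without quantile normalization the medians of these marks were 18.9, -6.24 and -4.72. Labels exchanged in the histone libraries alone are argued against by the odds ratios of type-specific EGR1 regions with type-specific regions of each mark. These were 16.1 for H3K27ac, 20.3 for H3K4me1 and 25.5 for H3K4me3, and 18.98, 20.2 and 25.1 with the same number of strongest peaks, where such an exchange needs ratios below 1. The H3K4me1 ratio was 8.71 with peaks of -log10 p of at least 3. An exchange in all libraries, EGR1 included, would leave these ratios as they are. Against it run the EGR1 medians of the excitatory and inhibitory lists, 2.33 (adjusted p = 0.00340) and -3.19 (adjusted p = 0.00382). The excitatory EGR1 median stays above 0 and past the threshold without each library in turn, with equal peak numbers and over gene bodies. The inhibitory EGR1 call is lost without inhibitory replicate 2 (adjusted p = 0.0578), with peaks of -log10 q of at least 5 (0.638) and among genes covered in all 4 libraries (0.320), and both EGR1 calls are lost with an estimated correlation (adjusted p = 0.635 each). In the direction of an exchange runs the H3K27ac median of the inhibitory list, 2.86 (adjusted p = 8.16e-04, and 0.635 with an estimated correlation). In the histone libraries the excitatory list is mixed. Its medians of 4.19 for H3K4me1 and 2.08 for H3K27ac lie in the labelled direction. Both calls are lost with an estimated correlation (adjusted p = 0.683 each), the H3K4me1 median is -1.40 at gene ends, and the H3K27ac adjusted p is 0.155 without excitatory replicate 1. Its H3K4me3 median is -9.94 with peaks of -log10 q of at least 5 (adjusted p = 2.57e-06), in the direction of an exchange. With those peaks, however, the granule H3K4me3 median is 9.22 (camera adjusted p = 0.693), so the granule pattern itself is not seen there. Without a known gate an exchange in all libraries stays open. Granule neurons among the nuclei labelled inhibitory remain a candidate explanation: a further list of 18 granule genes, none in the fixed lists, had an H3K4me3 median of -4.97 with 13 of 17 lower (camera p = 1.25e-05, and p = 0.0577 with an estimated correlation). The labels name a sort of nuclei and the Emx1-driven Cre but no gate, so whether granule nuclei were removed is open, as are other brain regions in the inhibitory nuclei, since HOX and thalamic genes had lower H3K4me1 in excitatory libraries too, although with an estimated correlation neither list passed (adjusted p = 0.678 and 0.635).

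The inhibitory neuron list had an H3K27ac median of 2.86 and an EGR1 median of -3.19, of opposite sign. The number of peaks called does not account for the difference in sign, since with the same number of strongest peaks the medians were 2.15 and -2.83. Weak enrichment of the excitatory H3K27ac libraries cannot be told apart from a difference between the cell types: with peaks of -log10 p of at least 3 the H3K27ac median was 0.977 (camera adjusted p = 0.300), above 0 but not past the threshold. The share of peaks with a q-value below 0.05 was 2.57% and 4.94% in those libraries against 31.8% and 35.1% in the inhibitory ones. A difference in H3K27ac between the cell types stays open and untested.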

How the results depend on the processing

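The alternatives with a -log10 p of at least 3, with the gene end holding more H3K4me3 and with coverage filters for gene lists were chosen after the data were seen, and the others before. Leaving out a library leaves 1 in a group, which is then assumed to vary like the others. Without depth, peak lists limit all results to what the authors' threshold called. With 2 libraries per group, leaving out a library also removes a residual degree of freedom. A limma call lost in this way therefore cannot be traced to the library left out. Of the values of main results under alternatives, 300 were counted as unchanged, 148 moved, 26 lost and 1 gained a call and 4 called values turned round. Of those that moved 9 changed sign without a call in the main analysis. For named genes the numbers were 4253, 89, 576, 217 and 7 (89 changes of sign without a call), for other gene lists 633, 164, 40, 11 and 5 (120), and for other relations 7, 21, 0, 0 and 2. For list medians and named genes, unchanged values kept the same side of the threshold and the same direction. For counts, lengths, overlap shares, Jaccard indices and correlations, unchanged means only that the change was small. Covered lengths and EGR1 overlap shares with 1 library left out were all counted as unchanged. Each is part of the mean it was compared with, so these cases do not measure stability. Except where said, the cause of a change was not tested.

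With the same number of strongest peaks, limma called 0 genes for H3K4me1 against 732, with 4025 at an unadjusted p under 0.05. Type-specific regions were 24213 and 26394 for H3K4me1 (excitatory and inhibitory), 12769 excitatory for H3K27ac, and 12053 and 6434 for EGR1. The H3K4me1 medians of the excitatory and inhibitory lists were 2.15 and 0.141, the excitatory H3K27me3 median was -0.103 against 0.380, and the Spearman correlations were 0.425 for H3K4me1 with H3K27ac and -0.352 for H3K27ac with H3K27me3. Without quantile normalization limma called 1211 genes for H3K4me1 and 0 for H3K4me3 (2344 unadjusted). The inhibitory list had an H3K27me3 median of -0.922 (adjusted p = 0.0259, in the direction higher than other genes) and the excitatory list one of -2.45. The granule list had an EGR1 median of 0.0719, which turned round in sign. All genes then had a median of 2.35, and the granule call was kept (camera adjusted p = 0.00458). The correlations were 0.507 for H3K4me1 with H3K27ac and 0.0861 for H3K27ac with EGR1. On the log2 scale 291 genes passed for H3K4me1, 0 for H3K4me3 (2774 unadjusted) and 1031 for H3K27me3.

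With the other gene window 219 genes passed for H3K4me1, 111 for H3K4me3 and 432 for EGR1. The H3K4me1 medians were -1.40 for the excitatory, -1.93 for the inhibitory, -4.32 for the granule, -4.30 for the glutamate receptor and -0.700 for the GABA list, and the excitatory H3K27ac median was 2.84. Differences turned round for Gabra2 (-7.86), Grik3 (-16.3), Grik4 (-3.38) and Ldb2 (-8.22) in H3K4me1 and for Dpp10 (-0.0420) and Nrxn3 (-1.45) in H3K4me3. With no filter on coverage 305 genes passed for H3K4me1, 256 for H3K4me3 and 2 for EGR1. Among genes covered in all 4 libraries 302 passed for H3K4me3 and 1167 for H3K27me3. There the medians were 1.36 for the excitatory, 1.99 for the inhibitory and -0.159 for the GABA list in H3K27ac, -0.885 for the excitatory and 2.94 for the granule list in H3K27me3, and -0.950 for the inhibitory and 0.590 for the granule list in EGR1, where both calls were lost. In H3K4me3 the granule median was -6.90 against -14.1, with 13 genes tested, and the thalamic -3.96 against -7.10. The thalamic H3K4me1 median was -4.37 against -7.28, and these calls were kept. The filter on all 4 libraries leaves out genes at 0 in a library, which is how the granule H3K27me3 genes in the inhibitory libraries are lost.

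With the replicate number as a block, 0 genes passed limma's test for H3K4me1 (4773 unadjusted), 1247 for H3K4me3 and 1329 for H3K27ac, and no other main call changed. The weight limma gives to the mean-variance trend, its prior degrees of freedom, went from 4.78 to 14.9 for H3K4me3. For H3K27ac it went from 3.41 to infinite, so each gene's own spread no longer entered those calls. Samples of the same number did not deviate together across genes (correlations 0.0595 for H3K4me1, 0.0477 for H3K4me3, 0.0145 for H3K27ac, 0.0282 for H3K27me3 and -0.0168 for EGR1), and with 2 libraries per group the numbers pair nothing.

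With peaks of -log10 p of at least 3, limma called 0 genes for H3K4me1 (540 unadjusted, of 3724 tested). Regions were 168 and 5328 for H3K4me1, 2808 and 7064 for H3K4me3, 5482 excitatory for H3K27ac and 13 and 147 for H3K27me3. List medians were 0.730 for the excitatory list in H3K4me1, 1.17 for the excitatory and 0.977 for the inhibitory list in H3K27ac. EGR1 overlap was 2.72%, 29.8%, 28.1% and 0.130% with H3K4me1, H3K4me3, H3K27ac and H3K27me3 in excitatory and 9.52%, 47.8%, 46.0% and 0.553% in inhibitory neurons. The odds ratio of EGR1 and H3K4me1 direction was 8.71, with 42 excitatory-specific and 463 inhibitory-specific H3K4me1 regions at excitatory EGR1 regions. Bivalent genes were 7 and 48, of which 2 and 30 had no H3K27me3 in the other type. Correlations were 0.317 for H3K4me1 with H3K27ac, 0.0485 for H3K4me1 with H3K27me3, which turned round, -0.287 for H3K27ac with H3K27me3 and 0.0718 for H3K27ac with EGR1. Within-type minus between-type Jaccard was 0.113 for H3K4me1, 0.103 for H3K4me3 and 0.114 for H3K27ac, against 0.149, 0.0609 and 0.0901.

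With peaks of -log10 q of at least 5 most broad peaks are gone, with covered lengths of 0.00155 and 0.00626 Mb for H3K4me1, 20.3 and 26.5 for H3K4me3, 0.0259 and 3.33 for H3K27ac, 0.00388 and 0.00306 for H3K27me3 and 28.4 and 11.1 for EGR1. Here limma called 0 genes for H3K4me3 (1251 unadjusted) and 529 for H3K27ac, and H3K4me1 and H3K27me3 could not be fitted. The H3K27ac count rests on quantile normalization of nearly empty excitatory libraries, with 14 and 42 peaks, and cannot be read as differences between the types. Regions were 0 and 0 for H3K4me1, 186 and 1797 for H3K4me3, 0 and 764 for H3K27ac, 1 and 1 for H3K27me3 and 16252 and 398 for EGR1. H3K4me3 list medians were -9.94 for excitatory genes, which then passed as lower in excitatory libraries (adjusted p = 2.57e-06), -6.65 for striatal, 9.22 for granule and -5.73 for GABA genes, and EGR1 medians -2.77 for inhibitory and -3.56 for granule genes, where both calls were lost. EGR1 overlap was 0.0037%, 25.4%, 0.0673% and 0.0086% in excitatory and 0.0129%, 66.2%, 11.1% and 0.0275% in inhibitory neurons. Bivalent genes were 2 and 0, with 2 and 0 specific. Correlations were -0.0838 for H3K4me3 with H3K27ac and 0.0723 for H3K27ac with EGR1, Jaccard differences 0.0388 for H3K4me1, 0.185 for H3K27me3 and 0.219 for EGR1, and the Fzd7 difference in H3K4me3 was 5.20. Odds ratios were infinite or had empty cells with this list, as was that of H3K27me3 at a -log10 p of at least 3, and were left out.

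With 50% of the region covered, H3K4me1 had 25539 inhibitory regions. With 50% of the EGR1 peak in a mark the shares were 61.7%, 34.9% and 11.6% for H3K4me1, H3K27ac and H3K27me3 in excitatory and 45.3%, 48.3%, 46.2% and 20.2% for H3K4me1, H3K4me3, H3K27ac and H3K27me3 in inhibitory neurons. At gene ends of 1 kb, 2880 inhibitory genes were bivalent and 383 were specific. With the promoter window for all antibodies the correlations were 0.242 for H3K4me1 with H3K27ac, -0.290 for H3K27ac with H3K27me3 and 0.134 for H3K27ac with EGR1. With an estimated correlation 10 calls of the excitatory, inhibitory and granule lists were lost at medians that do not change by construction: 4.19 and -7.97 in H3K4me1, -14.1 in H3K4me3, 2.08, 2.86 and -4.27 in H3K27ac, 20.8 in H3K27me3, and 2.33, -3.19 and -2.97 in EGR1. With a robust variance no count of calls moved by over 1.5 times. The alternatives of the EGR1 motif were not run.

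Leaving out each library in turn gave 0 to 507 limma calls for H3K4me1 (2737 to 4826 unadjusted), 0 to 733 for H3K4me3 (1396 to 3280) and 0 to 925 for H3K27ac (1043 to 5675). Regions ranged, by construction upwards since fewer libraries must agree, from 68024 to 174292 and 21510 to 74468 for H3K4me1 (excitatory, inhibitory), 8472 to 115299 and 12685 to 112804 for H3K4me3, 27511 to 204271 and 20589 to 52568 for H3K27ac, 32275 to 91906 and 49521 to 157597 for H3K27me3 and 34525 to 51802 and 4855 to 17798 for EGR1. List medians ranged from -1.05 to 2.81 for excitatory and -4.37 to 0.0174 for inhibitory genes in H3K4me3, -0.326 to 1.57 for excitatory genes in H3K27me3, 1.08 to 3.09 for excitatory genes in H3K27ac, 2.15 to 4.24 for inhibitory genes in H3K27me3, 0.946 to 3.13 for excitatory genes in EGR1, -4.58 to -2.72 for inhibitory genes in EGR1 and -4.70 to -1.78 for granule genes in EGR1.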

Other observations

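The further gene lists and the genes of lists named here by a test of the list alone were chosen after the main results were seen. Further granule neuron genes outside the fixed lists had an H3K4me1 median of -5.15 points with 15 of 18 lower in excitatory libraries (camera p = 3.07e-04, and p = 0.130 with an estimated correlation) and an H3K27ac median of -2.86 with 17 of 18 lower (camera p = 7.46e-05, and p = 0.0798 with an estimated correlation). Their H3K27me3 median was 11.1 with 16 of 17 higher (camera p = 2.46e-08, and p = 0.0349 with an estimated correlation), and 10 of them rose adjusted over the list alone. For EGR1 they had -0.805 (camera p = 0.810, and p = 0.825 with an estimated correlation). The 15 genes of the granule list that no other list holds had medians of -14.5 for H3K4me3 (camera p = 1.42e-11, and p = 0.0275 with an estimated correlation), 21.9 for H3K27me3 (camera p = 4.72e-07, and p = 0.0331 with an estimated correlation), -9.61 for H3K4me1 (camera p = 8.51e-05, and p = 0.124 with an estimated correlation), -4.61 for H3K27ac (camera p = 5.33e-04, and p = 0.118 with an estimated correlation) and -3.62 for EGR1 (camera p = 0.00294, and p = 0.177 with an estimated correlation). Genes of Purkinje cells, the GABAergic projection neurons of the cerebellum, had camera p-values of 0.751 for H3K4me1, 0.692 for H3K4me3, 0.784 for H3K27ac, 0.444 for H3K27me3 and 0.591 for EGR1.

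Among immediate early genes, the list of which passed for no antibody, Arc, a gene of the synapse, and Npas4, an activity-dependent transcription factor gene, had H3K27ac differences of -15.8 ± 3.29 and -9.40 ± 1.83 (SE, limma adjusted p = 0.144 each), and Klf4 8.65. In H3K27me3 coverage Ier2 had a difference of 24.3 and the phosphatase gene Dusp6 -30.1. Of the chromatin-modifying enzymes, Kdm6b, a demethylase gene for H3K27, had an EGR1 difference of 13.4 (limma adjusted p = 0.107), and Kdm6a, an X-linked relative, an H3K4me1 difference of -12.8 ± 2.34 (limma adjusted p = 0.0491). Among glial and vascular genes, Fcrls, a microglial gene, rose by 11.6 points in H3K4me1 and Cldn5, a tight junction gene of endothelium, by 12.1. For H3K4me3, P2ry13, a microglial receptor gene, and Cdh5, the cadherin gene of endothelium, fell, with -11.3 and -10.9. The monoaminergic and cholinergic list did not pass for H3K4me1, with a median of -1.32 (camera adjusted p = 0.559), and adjusted over the list alone 4 members rose and 7 fell. Foxa1 and Foxa2, of midbrain dopaminergic development, had differences of -18.1 and -17.2, En1, a homeobox gene of midbrain and cerebellum, -16.8, and Dbh, which encodes a noradrenaline-synthesizing enzyme, 14.7.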
